A study of Scophthalmus maximus with 30 samples.

How the data were processed

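Gonads of 30 turbot were dissected and flash frozen, and total RNA was extracted from each fish, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels. Each scanner file holds the spot intensities of 1 array as deposited by the authors, made with Agilent Feature Extraction 9.5.1.1, per the file headers. The processed intensity is background-subtracted and detrended within the array, with a surrogate value for spots near the background, per the file headers, and is not normalized between arrays. The mean intensity of the spot and the median of its local background are uncorrected, per the file headers. Flags of the scanner software mark spots well above background, saturated spots and outlier spots. The authors also deposited a table of processed intensities on a linear scale, with medians between 250.5 and 313 per column (most near 310) and 8.17% to 62.6% of the values blank per column. The submitters' processing notes name limma and R 3.0.2. How that table was background-corrected, normalized and filtered is not given in the sources used here, and it was used as an alternative.

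Every column of the value table was set against all 30 scanner files. Of the 30 columns, 18 matched their own fish's file best and 12 matched another file of the same slide, 4 of them a file of another group. The main analysis took each file's fish from the deposited records of the scanner files. Whether those records or the table's columns hold the right assignment could not be settled here, so the counts are also given under the table's assignment and without the 4 arrays assigned to different groups.

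Groups came from the labelled stage of gonad development: 4 pre-undifferentiated, 7 undifferentiated and 8 differentiating fish, 5 male and 6 female juveniles. Each array holds 43803 probe spots with 40398 distinct sequences of 55 to 60 bases, of which 37073 lie on 1 spot, 3315 on 2 and 10 on 10 spots. Control spots were left out, and spots of 1 sequence were averaged. Outlier spots, at most 22 per array, were left out where the sequence had another spot without that flag, and kept otherwise. The SD between repeat spots of the sequences on 10 spots had a median of 0.320 on the log2 scale. Values are the log2 processed intensity minus the array's 75th percentile. Probes well above background on at least 4 arrays were tested, 37777 in all. No probe has a gene name in the files, and the table of gene symbols at hand holds no probe or sequence, so fixed lists of sex, germ cell and tissue marker genes, and the genes named in advance, were not analysed here.

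Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) over all 30 arrays, with the 5 groups as the model and no covariate, and Benjamini-Hochberg adjustment at 0.05. The comparisons, the alternatives, the score and the rule for named probes were fixed before the data were examined, except where the text says otherwise. The named probes are, with no gene names, the 2 highest and 2 lowest log2 fold changes per comparison among probes past the threshold whose values do not overlap between the groups. A probe not well above background on every array of a group has only a bound there. Its fold is the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, and is written "at least". For R4_25357 and R4_55133 the bright group also held arrays not well above background. Their own values entered its mean, so the fold there is not a strict bound and is given without "at least". The score took 200 probes per direction by limma's t between the juvenile sexes, with 50 as an alternative, and its spread was tested with an exact permutation test. Probe sets were tested with camera (preset correlation), with an estimated correlation and with fry. The sets were chosen after it was clear that no gene list could be tested.

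Alternatives were normexp background correction (offset 50), quantile and median scaling, the value table, other filters, the 2 groups alone, array weights, a trended and robust variance, a 2-fold threshold, blocks for replicate number, slide and scan campaign, age classes, spike-in scaling and leaving out each fish. The 11 slides were scanned in 2 campaigns of 18 and 12 arrays. Slide as a fixed block left out the pre-undifferentiated fish, and as a random block the consensus correlation was 0.167. Differentiating fish 5 to 8 filled 1 slide, and female juveniles 2 and 6 shared another with no other group. With slide as a fixed block these fish add nothing to the differences between groups. A call lost there can thus reflect fewer fish as well as slide. The fit was tested on simulated data with 200 of 37777 probes changed per comparison. It recovered 2% to 11% of 2-fold changes and 45% to 62% of 4-fold changes, with 2 to 7 false calls and 0 wrong signs per comparison. The Benjamini-Hochberg cut depends on the share of probes that change. In the data 18.7% were called in differentiating against undifferentiated fish, and 57.8% and 61.3% in female juveniles against differentiating fish and males. The rates do not describe those comparisons.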

Results

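The data followed the gonad of turbot (Scophthalmus maximus), a farmed flatfish, from before the sexes can be told apart to sexed juveniles. One-colour Agilent arrays measured RNA from 30 gonads, each extracted individually, so that p-values reflect the spread between fish. The labels placed 4 fish in the pre-undifferentiated stage at 76 days post hatching and 7 in the undifferentiated stage at 89 to 91 days. A further 8 fish were differentiating at 135 to 151 days, and carried no label of sex. The juveniles, aged 309 to 485 days, were 5 males and 6 females. Of 40398 distinct probe sequences, 34552 ± 608 (mean ± SD, n = 4) stood well above background in pre-undifferentiated fish, 30596 ± 2795 (n = 7) in undifferentiated fish, 35649 ± 1426 (n = 8) in differentiating fish, 29955 ± 4793 (n = 5) in male juveniles and 27409 ± 7254 (n = 6) in female juveniles. Female juvenile 1 had the fewest, 15099. The number of arrays limits the precision of each comparison. The files pair no probe with a gene, so probes are named by identifier and sequence, and no gene or cell type is named.

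The 2 deposited sources disagreed on which array belonged to which fish on 3 slides. For 18 fish, the column of the authors' value table matched the fish's own scanner file best (r between 0.979 and 1.000 across probes). For the other 12 fish, which filled the slides of the second of 2 scan campaigns, the column matched the scanner file of another fish on the same slide (r between 0.997 and 0.999), and its own file with an r between 0.684 and 0.972. The exchange stayed within the group for 4 pre-undifferentiated and 4 differentiating fish. It crossed groups for the undifferentiated fish aged 91 days (replicates 6 and 7) and male juveniles 5 and 6. Values below follow the scanner files as deposited. The number of probes passing in each comparison is given again with the files assigned as in the value table, and without these 4 arrays, which leaves only exchanges within a group. Both alternatives were chosen after seeing the data.

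Female juveniles stood apart from male juveniles and from the 2 youngest stages, but the arrays deposited as differentiating fish 5 and 7 lay among them. These had mean correlations of 0.916 and 0.911 with the female juveniles, against 0.893 for female juvenile 1 with the other females. The first principal component held 51.2% of the variance. Pre-undifferentiated fish correlated with each other at a mean r of 0.961 across probes, and with undifferentiated fish at 0.870. Female juveniles correlated with each other at a mean r of 0.932, with male juveniles at 0.640 and with differentiating fish at 0.728. Male juveniles correlated with differentiating fish at a mean r of 0.836, against 0.858 among themselves. Undifferentiated fish 6 and 7, on the disputed slide, had a mean r of 0.745 with the pre-undifferentiated fish, against 0.920 for the 5 fish aged 89 days.

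**Figure D1:**
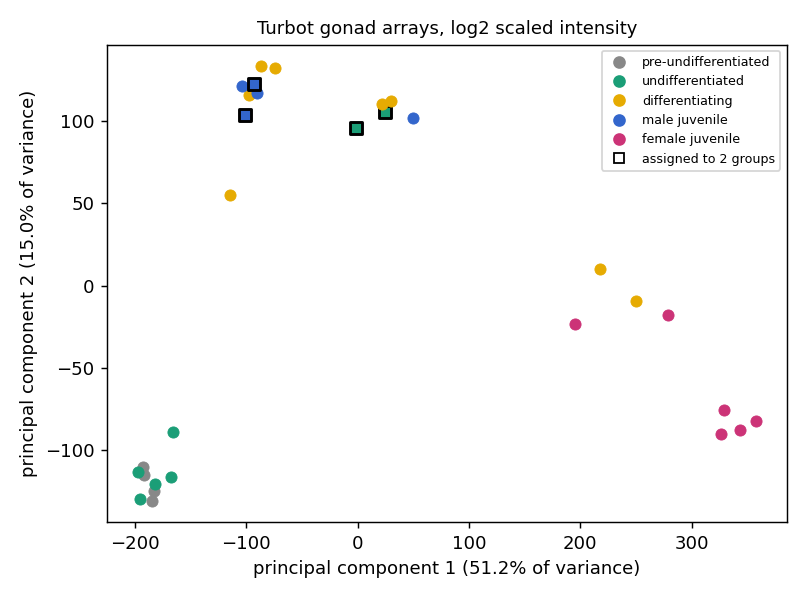
The first and second principal components of the log2 scaled intensities, as percent of variance on each axis, 1 point per array, coloured by group, with black squares for the 4 arrays that the 2 sources assign to different groups. Female juveniles lie at the right, from 195 on the first component upward, together with the arrays of differentiating fish 5 and 7 at 249.9 and 217.4. The pre-undifferentiated fish lie at the lower left with the undifferentiated fish aged 89 days.

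The first comparison asked what changed in the gonad before differentiation was visible. Most of the called probes were lower in the undifferentiated than in the pre-undifferentiated stage, by a margin that depended on the fit. Probe R4_62224 (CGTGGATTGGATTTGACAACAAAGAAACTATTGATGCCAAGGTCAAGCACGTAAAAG) had a log2 value of 5.19 ± 0.98 (SD, n = 4) in pre-undifferentiated fish and was not well above background on any of 7 undifferentiated arrays. With the files as deposited it was at least 917-fold lower in undifferentiated fish (limma adjusted p = 7.62e-13). It was not well above background on any of the 8 differentiating arrays either, but was on 2 male and 2 female juvenile arrays. These 2 male arrays are the disputed ones of male juveniles 5 and 6, at -2.29 and -3.02. The value table assigns them to undifferentiated fish, and the bound does not cover that assignment. The call held in all 29 alternatives. Probe R4_62703 (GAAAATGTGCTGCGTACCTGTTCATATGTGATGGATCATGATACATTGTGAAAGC) fell by 9.68 on the log2 scale (SE 0.83, limma adjusted p = 1.90e-08), from 4.04 ± 0.84 (SD, n = 4), and 1 of 7 undifferentiated arrays measured it above background, so that the size of the fall rests mostly on values near the background. Probe R4_6870 (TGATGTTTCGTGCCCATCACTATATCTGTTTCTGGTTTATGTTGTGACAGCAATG) rose by 3.62 (SE 0.54, limma adjusted p = 0.000268), to 0.76 ± 1.18 (SD, n = 7). Probe R4_25357 (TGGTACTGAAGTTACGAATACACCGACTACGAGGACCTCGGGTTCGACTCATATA) was not well above background in pre-undifferentiated fish. By the rule for bounds it was 11.8-fold higher in undifferentiated fish (limma adjusted p = 0.0281), of which 5 of 7 arrays measured it. Undifferentiated fish 6 and 7 entered that mean at -5.60 and -5.95, not well above background, so the fold is not a strict bound. The probe lost its call in 12 of 27 alternatives. The log2 change there was 5.08 with the files assigned as in the value table (adjusted p = 0.0671), 1.90 with normexp background correction (adjusted p = 0.276), 5.43 with slide as a random block (adjusted p = 0.0763) and 2.46 with the scan campaign as a block (adjusted p = 0.115), and leaving out 1 fish ended the call in 7 of 11 cases. No pre-undifferentiated array measured the probe, so these fitted sizes are set against values near the background.

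Of 37777 probes tested, 366 passed an adjusted p of 0.05 in limma, 27 higher and 339 lower in undifferentiated fish, and 365 differed by at least 2-fold. All pre-undifferentiated arrays and no undifferentiated array measured 124 probes above background, against 1 probe the other way. Array signal favours that direction, with 34552 ± 608 (SD, n = 4) probes above background on pre-undifferentiated and 30596 ± 2795 (SD, n = 7) on undifferentiated arrays. The count was 230 with the files assigned as in the value table (15 higher, 215 lower) and 305 without the 4 disputed arrays (34 higher, 271 lower). It fell to 182, 138 and 131 when pre-undifferentiated fish 1, 3 or 4 was left out. All pre-undifferentiated fish shared 1 slide with no other group, so slide could enter only as a random block, which gave 108 probes (5 higher, 103 lower). Stage and slide are thus confounded, and no fit can tell a slide effect from the stage change in these counts or named probes. With the scan campaign as a block 654 probes passed, 132 higher and 522 lower, and with array weights 4823, 1664 higher and 3159 lower. Within the second campaign, which holds only undifferentiated fish 6 and 7 of that group, 15792 passed, 7528 higher and 8264 lower.

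The second comparison asked what changed as the gonad began to differentiate. The 2 named probes that rose were both higher still in female juveniles. Probe R4_626 (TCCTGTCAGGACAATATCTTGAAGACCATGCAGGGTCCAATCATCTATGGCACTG) was not well above background on any undifferentiated array, and reached 0.40 ± 4.59 (SD, n = 8) in differentiating fish. It was at least 33.1-fold higher there (limma adjusted p = 0.000508), and its mean was 6.64 ± 0.16 (SD, n = 6) in female juveniles against -3.97 ± 1.76 (SD, n = 5) in males. Probe R4_28429 (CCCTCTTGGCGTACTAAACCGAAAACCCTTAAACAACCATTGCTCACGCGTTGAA) rose by 5.42 (SE 1.05, limma adjusted p = 0.000839), to 0.68 ± 3.84 (SD, n = 8), from a stage where 3 of 7 arrays measured it above background, and stood at 6.73 ± 0.50 (SD, n = 6) in female juveniles. With slide as a block their log2 changes were 4.47 (limma adjusted p = 0.105) for R4_626 and 3.33 (limma adjusted p = 0.173) for R4_28429, no longer past the threshold. Differentiating fish 5 to 8, which filled 1 slide, add nothing to the difference in that fit. Within the second campaign the changes were 8.53 (limma adjusted p = 0.203) and 7.86 (limma adjusted p = 0.225). Fitted sizes are set against values near the background where no undifferentiated array measured the probe. This holds throughout for R4_626, and within the second campaign for R4_28429 too. The arrays of differentiating fish 5 and 7 stood apart for both, at 7.05 and 6.39 against -5.15 to 2.07 on the other 6 for R4_626, and as the 2 highest, with 7.15 on fish 5, against -2.54 to 0.77 for R4_28429. Without fish 5 the fitted log2 changes went from 6.73 to 5.78 and from 5.42 to 4.50, both still past the threshold. Probe R4_10615.1 (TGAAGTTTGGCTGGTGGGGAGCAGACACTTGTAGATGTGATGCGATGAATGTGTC) fell by 7.04 (SE 1.05, limma adjusted p = 7.55e-05), from 4.69 ± 3.76 (SD, n = 7) to -2.35 ± 1.05 (SD, n = 8), and the log2 difference was -9.13 without the 4 disputed arrays. Within the second campaign it was -2.42 (adjusted p = 0.214), where undifferentiated fish 6 and 7, the only 2 of their group, read -0.42 and -0.67. Probe R4_55133 (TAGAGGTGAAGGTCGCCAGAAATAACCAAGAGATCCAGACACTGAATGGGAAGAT) was not well above background on any differentiating array. By the rule for bounds it was 32.9-fold lower there than in undifferentiated fish (limma adjusted p = 2.78e-05), of which 5 of 7 arrays measured it. Undifferentiated fish 6 and 7 entered that mean at -5.44 and -5.95, not well above background, so the fold is not a strict bound. Within the second campaign no array of either group measured R4_55133. The difference fitted there (-2.29, limma adjusted p = 0.166) lies between background values and could not test the fall.

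Of the probes tested, 7058 passed in limma, 3194 higher and 3864 lower in differentiating fish, and 5928 of them differed by at least 2-fold. All 8 differentiating arrays and no undifferentiated array measured 71 probes above background, and none did the opposite. Array signal favours that direction, with 35649 ± 1426 (SD, n = 8) probes above background on differentiating and 30596 ± 2795 (SD, n = 7) on undifferentiated arrays. The count was 7900 with the files assigned as in the value table (3759 higher, 4141 lower) and 10876 without the 4 disputed arrays (5448 higher, 5428 lower). With slide as a block, where differentiating fish 5 to 8 add nothing to the difference, it was 3838. Within the first scan campaign it was 10253, with 4272 higher. Within the second, where only undifferentiated fish 6 and 7 stood against 4 differentiating fish, it was 0 in limma. The split leaned further to lower with normexp background correction (1831 higher, 9112 lower). It turned with scaling to the spike-ins (25300 higher, 862 lower), with array weights (6802 higher, 6560 lower) and on the value table (4540 higher, 1572 lower).

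Probes that rose in differentiating fish overlapped with those higher in female juveniles, with a larger share over all 8 fish than within the first scan campaign, a difference that was not tested. Of the 3194 probes higher in differentiating fish, 1631 (51.1%) were also higher in female than in male juveniles, where independent lists would share 906. Only 623 were higher in males, against 1052 for independent lists. Of the 3864 lower probes, 319 were female-higher against 1096, and 1304 were male-higher against 1272. The 2 comparisons shared no array in their differences, but the SE of both came from the spread within all 5 groups. Probes with a small spread are thus more likely to be called in both, which the counts for independent lists do not allow for. With the files assigned as in the value table, 2327 of the 3759 higher probes were female-higher (1016 for independent lists), and without the 4 disputed arrays 2729 of 5448 (1482 for independent lists). Differentiating fish 5 and 7, whose arrays lay among the females, are both of the second campaign. All differentiating fish of that campaign were 135 days old, against 137 to 151 days in the first, so a split by campaign also divides ages. Within the first campaign, with 4 differentiating and 5 undifferentiated fish, 1447 of 4272 higher probes (33.9%) were female-higher, against 1212 for independent lists, and 1489 were male-higher, against 1407. Of the 5981 lower probes there, 865 were female-higher against 1697, and 1700 were male-higher against 1969. This split was chosen after seeing the data.

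Sets of 200 probes each were then taken by limma's t between the juvenile sexes, those highest in females (ovary-high) and in males (testis-high). The difference in that t came from the juveniles alone, but its SE came from the spread within all 5 groups. Probes that vary widely within the earlier stages were thus less likely to be chosen, and the sets are not independent of those stages. Of the ovary-high probes, 40 rose and 1 fell from undifferentiated to differentiating fish, with a median log2 change of 0.71 (camera adjusted p = 2.49e-09, but adjusted p = 0.961 with an estimated correlation, and fry adjusted p = 0.221). The mean of the ovary-high probes was 0.80 and 0.44 on the arrays of differentiating fish 5 and 7, and from -2.70 to -1.66 on the other 6, against -2.70 to -2.38 in undifferentiated fish. Within the first campaign 16 ovary-high probes rose and 14 fell (median 0.33), and 23 testis-high probes rose and 13 fell (median 0.28). Over all fish, 13 testis-high probes rose and 15 fell, with a median of 0.11 (camera adjusted p = 0.764). From pre-undifferentiated to undifferentiated fish, 1 ovary-high probe rose and none fell (median 0.10, camera adjusted p = 0.266). Of the testis-high probes none rose and 3 fell there (median -0.35, camera adjusted p = 7.16e-05, but adjusted p = 0.961 with an estimated correlation). Sets chosen with the files assigned as in the value table gave 57 ovary-high probes that rose and 0 that fell between undifferentiated and differentiating fish, and 3 testis-high probes that rose and 45 that fell. Without the 4 disputed arrays 57 ovary-high probes rose and 9 fell there, and 21 testis-high probes rose and 16 fell.

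The mean of the ovary-high probes minus that of the testis-high probes gave each fish an ovary-minus-testis score on the log2 scale. The score was -2.33 ± 0.18 (SD, n = 4) in pre-undifferentiated fish, -1.95 ± 0.25 (n = 7) in undifferentiated fish and -1.05 ± 2.19 (n = 8) in differentiating fish. In the juveniles, whose difference entered the choice of the probes, it was -2.88 ± 0.59 (n = 5) in males and 5.36 ± 0.93 (n = 6) in females. The differentiating fish ranged from -2.98 to 2.69, and the arrays deposited as differentiating fish 5 and 7 had 2.69 and 2.04. Their mean absolute deviation from the stage's median was 1.54, against 0.20 in undifferentiated fish. The difference of 1.35 had a two-sided exact permutation p of 0.0169 over 6435 splits, which did not pass after Benjamini-Hochberg adjustment over the 3 stage pairs (adjusted p = 0.0508). Against pre-undifferentiated fish the exact permutation p was 0.0929 (adjusted 0.139), and undifferentiated against pre-undifferentiated fish gave 0.536.

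**Figure D2:**
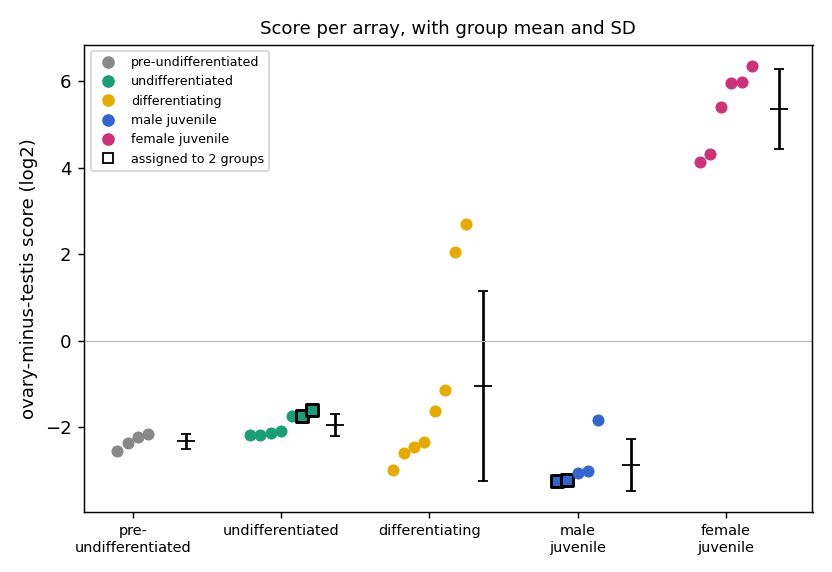
The ovary-minus-testis score (log2) of each array by group, with the group's mean and SD as a bar beside the points and black squares for the 4 arrays that the 2 sources assign to different groups. The differentiating fish range from -2.98 to 2.69, while the undifferentiated fish lie between -2.18 and -1.60.

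The third comparison set male juveniles against differentiating fish, and no probe passed in limma. The smallest adjusted p was 0.194, while 4498 probes had an unadjusted p under 0.05. No probe was above background in all male juveniles and in no differentiating fish, and 13 were the other way round. Array signal favours that direction: male juvenile 1 measured 22836 probes above background, against 33038 to 37102 on the differentiating arrays. Other settings gave 18 probes with the files assigned as in the value table, 0 without the 4 disputed arrays, 52 on the value table itself and 83 with array weights. With slide as a block, and within the first scan campaign, the count was 0, and within the second campaign it was 3. Differentiating fish 5 and 7, whose arrays lay among the females, belonged to the group compared in the main fit. The first campaign lacks them but holds fewer fish. On simulated data the fit recovered 11% of 2-fold and 49% of 4-fold changes in this comparison. A count of 0 thus does not show that nothing changed. Probe R4_626, chosen here because it is named above, had -3.97 ± 1.76 (SD, n = 5) in male juveniles and 0.40 ± 4.59 (SD, n = 8) in differentiating fish.

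The fourth comparison set female juveniles against the same differentiating fish. The probes that rose furthest were already measured above background on 6 of the 8 differentiating arrays. Probe R4_522.1 (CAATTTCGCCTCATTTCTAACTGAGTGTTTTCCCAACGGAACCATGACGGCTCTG) rose by 8.59 (SE 1.35, limma adjusted p = 1.39e-05), from -2.10 ± 4.91 (SD, n = 8) to 6.50 ± 0.51 (SD, n = 6). Probe R4_22405r.1 (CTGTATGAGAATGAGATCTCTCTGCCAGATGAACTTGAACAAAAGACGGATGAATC) rose by 8.40 (SE 1.45, limma adjusted p = 3.53e-05), to 6.61 ± 0.42 (SD, n = 6). The differentiating mean of both rested in part on fish 5 and 7, which read 4.94 and 5.11 for R4_522.1 against -7.84 to -1.22 on the other 6 arrays, and 5.49 and 5.39 for R4_22405r.1 against -8.03 to -0.99. Without fish 5 the rises were 9.60 and 9.44, and without fish 7 9.62 and 9.42. Probe R4_22288 (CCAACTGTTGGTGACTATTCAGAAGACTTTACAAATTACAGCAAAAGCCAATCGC) was not well above background on any female juvenile array, and was at least 18.5-fold lower there (limma adjusted p = 2.19e-05) than in differentiating fish, which had -0.21 ± 1.39 (SD, n = 8). Probe R4_30170r (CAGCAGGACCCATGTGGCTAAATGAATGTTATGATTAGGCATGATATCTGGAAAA) fell by 5.90 (SE 1.05, limma adjusted p = 4.86e-05), from 0.58 ± 2.46 (SD, n = 8), and 1 of 6 female arrays measured it above background, so that the size rests mostly on values near the background. With slide as a block the log2 changes were -4.25 (limma adjusted p = 0.105) for R4_22288 and -5.15 (limma adjusted p = 0.0555) for R4_30170r, no longer past the threshold. Differentiating fish 5 to 8 and female juveniles 2 and 6 add nothing to the difference in that fit. No female array measured R4_22288, so the size of its fitted change is set against values near the background.

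In all, 21841 probes passed in limma, 10325 higher and 11516 lower in female juveniles, and 18940 differed by at least 2-fold. All differentiating arrays and no female array measured 329 probes above background, and no probe was the other way round. Array signal favours that direction: female juvenile 1 measured 15099 probes above background, against 33038 to 37102 on the differentiating arrays. The count was 22002 with the files assigned as in the value table, 23127 without the 4 disputed arrays and 10902 with slide as a block. The fit with slide as a block rests on fewer fish, since differentiating fish 5 to 8 and female juveniles 2 and 6 add nothing there. Within the first scan campaign, which holds all females, the count was 23344. The split turned with scaling to each array's median (12968 higher, 9074 lower) and to the spike-ins (13933 higher, 5763 lower), with normexp (10686 higher, 8656 lower) and with no filter on dim probes (12295 higher, 11524 lower). The value table gave 13969, 3184 higher and 10785 lower. The difference between this change and that of the males is the direct comparison of the sexes.

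The fifth comparison asked how ovary and testis differ in sexed juveniles. Probe R4_51131 (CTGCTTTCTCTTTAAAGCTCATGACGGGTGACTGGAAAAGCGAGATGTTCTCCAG) had 6.23 ± 0.89 (SD, n = 6) in females and was not well above background on any male array. It was at least 1696-fold higher in females (limma adjusted p = 1.15e-06). Probe R4_22405r.1 was higher in females by 12.08 (SE 1.63, limma adjusted p = 1.60e-06), at 6.61 ± 0.42 (SD, n = 6) against -5.47 ± 1.85 (SD, n = 5), where 1 of 5 male arrays measured it above background, so that the size rests mostly on values near the background. Probe R4_12965.1 (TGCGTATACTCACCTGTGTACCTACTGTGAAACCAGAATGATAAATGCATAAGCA) was lower in females by a log2 difference of -7.18 (SE 0.82, limma adjusted p = 5.24e-07), at -5.16 ± 2.17 (SD, n = 6) against 2.02 ± 1.05 (SD, n = 5), and 2 of 6 female arrays measured it above background, so that the size rests mostly on values near the background. Probe R4_12761r (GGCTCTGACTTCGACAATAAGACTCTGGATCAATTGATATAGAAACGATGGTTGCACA) differed by -7.12 (SE 1.92, limma adjusted p = 0.00218), and by -9.91 with the files assigned as in the value table, and again 2 of 6 female arrays measured it above background. The difference was -5.59 with slide as a block (adjusted p = 0.0667) and -6.85 among juveniles aged 309 to 315 days (adjusted p = 0.0606), both short of the threshold. For this probe the disputed arrays of male juveniles 5 and 6, both aged 315 days, read -2.33 and -2.07, against 2.56 to 5.76 in males 1, 3 and 4. The disputed undifferentiated fish 6 and 7 read 4.62 and 4.92, against -4.85 to -3.02 in the fish aged 89 days. The male mean thus mixes 2 levels that split along the disputed arrays. The probes R4_51131 and R4_22405r.1 were at -2.04 ± 5.09 and -1.79 ± 5.09 (SD, n = 8) in differentiating fish. Differentiating fish 5 and 7 stood apart for R4_51131, at 5.82 and 5.11 against -7.70 to -1.19 on the other 6 arrays, as they did for R4_22405r.1.

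**Figure D3:**
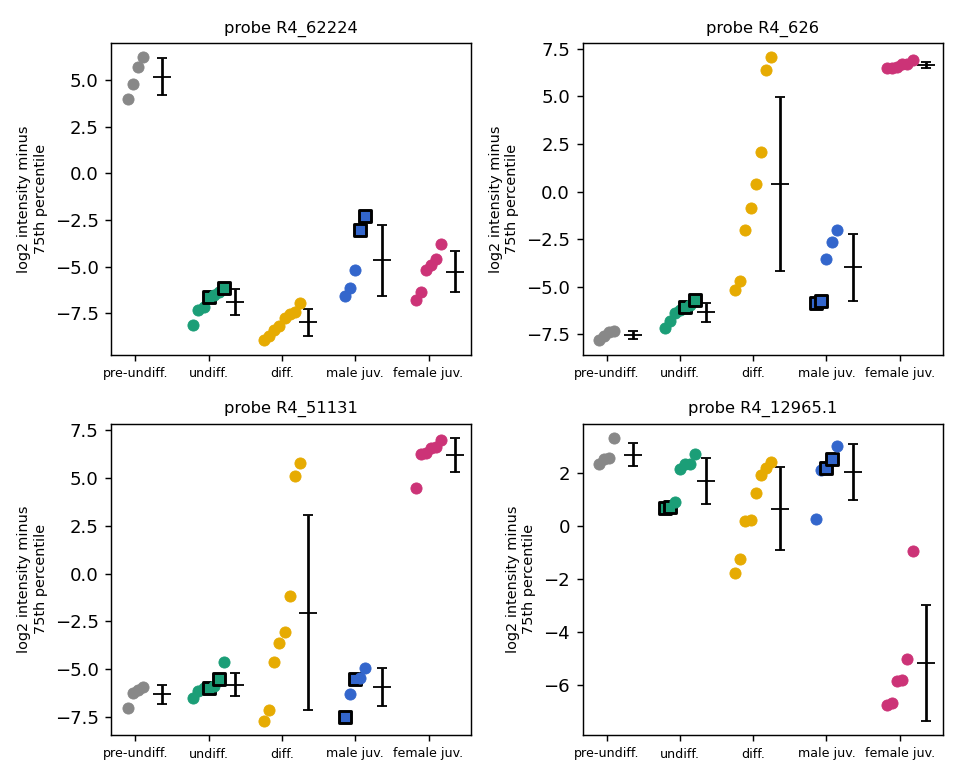
Log2 intensity minus the array's 75th percentile for probes R4_62224, R4_626, R4_51131 and R4_12965.1, 1 point per array by group, with the group's mean and SD as a bar beside the points and black squares for the 4 arrays that the 2 sources assign to different groups. R4_62224 is bright in the 4 pre-undifferentiated fish, R4_626 and R4_51131 in the 6 female juveniles and in some differentiating fish, and R4_12965.1 is dimmest in female juveniles.

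Of the probes tested, 23156 (61.3%) passed in limma, 10718 higher and 12438 lower in females, and 21305 differed by at least 2-fold. Differences of at least 32-fold were fitted for 690 probes higher in females and 108 higher in males. Of all 37777 probes tested, 14156 had no overlap between the values of the sexes, where chance gives 0.433% of probes. Of these, 14010 were called. All females and no male measured 180 probes above background, against 32 the other way. The count was 21307 with the files assigned as in the value table, 21358 without the 4 disputed arrays and 20386 with slide as a block. Within the first scan campaign it was 19402, and it was 12710 of 35151 probes tested on the value table. It was 19078 among juveniles aged 485 days, 9790 higher and 9288 lower, and 11762 among those aged 309 to 315 days. With scaling to the median the split was 12745 higher and 10363 lower, and with scaling to the spike-ins 16192 higher and 5163 lower.

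**Figure D4:**
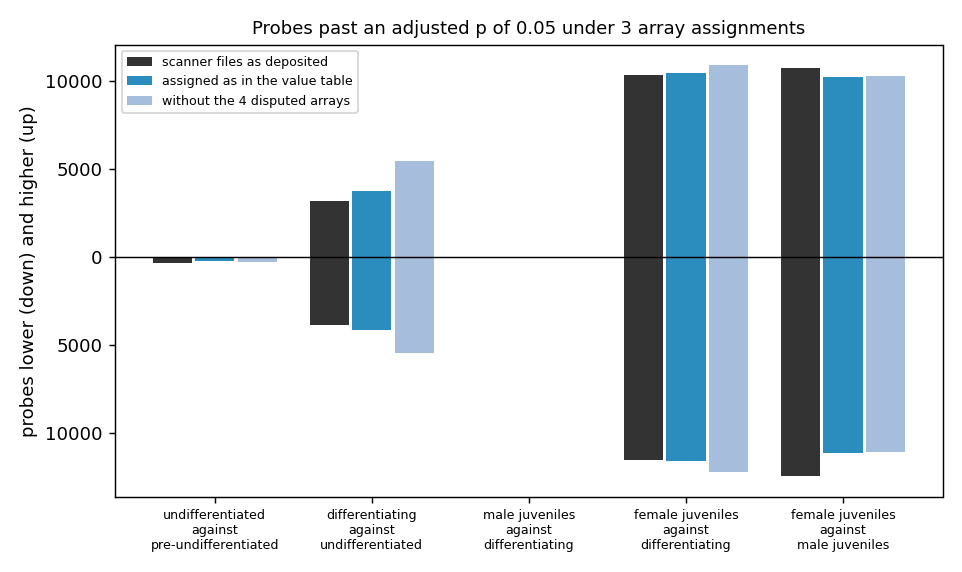
Number of probes past an adjusted p of 0.05 in each comparison, higher in the first group above the line and lower below it, for the scanner files as deposited, assigned as in the value table, and without the 4 disputed arrays. The comparisons with female juveniles have 21307 to 23156 probes against males and 21841 to 23127 against differentiating fish under all 3, and male juveniles against differentiating fish has 0, 18 and 0.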

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

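The tests of slide and brightness for the score, of scan year and of an exchange for the fish aged 91 days, of slide for the sexes, and all results under the value table's assignment, were chosen after the result was seen.

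The 2 undifferentiated fish aged 91 days stood apart from the 5 aged 89 days, with 11034 probes called between them (limma, 2 against 5 fish), and the change from undifferentiated to differentiating fish differed between scan campaigns in 4698 probes (an interaction in limma). It did so in 2736 probes with the files assigned as in the value table. Age split along the campaigns in both groups, with differentiating fish at 135 days in the second campaign and 137 to 151 days in the first. The interaction thus cannot tell age from campaign. A slide effect predicts that the male juveniles of that slide deviate over the same probes, but the slope was -0.0177, and 0.0916 with the value table's assignment. An effect of scan year predicts a closer match with the pre-undifferentiated fish, scanned in the same campaign, but their mean correlation was lower by a difference of -0.174, and by -0.0982 with the value table's assignment. An exchange with the 2 male juveniles of the slide would give arrays like the fish aged 89 days, but those arrays' mean correlation with them was 0.805, at a difference of -0.0820 from the lowest between 2 fish aged 89 days, with 6020 probes still called, so an exchange alone does not account for the gap. Whether arrays were exchanged stays open: 0.805 exceeds the 0.739 of the arrays deposited as undifferentiated, while with the 3 other male juveniles the arrays deposited as males correlated better (0.853 against 0.823), and a mix-up with other samples or a difference in development was not tested.

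The spread of the ovary-minus-testis score among differentiating fish came from the arrays deposited as fish 5 (2.69) and 7 (2.04), with the other 6 between -2.98 and -1.13. Both lie on the slide that holds 4 differentiating fish, whose range was 100% of the range over all 8, so a slide effect shared by its arrays does not account for it. Among the other 6 arrays the score rose with brightness, short of the threshold (Pearson r 0.799, exact permutation p = 0.0625; Spearman rho 0.829, exact permutation p = 0.0583, 1 relation computed), and without the 2 arrays farthest in brightness r was 0.305. The 2 high arrays lay at least 8.20 residual SDs above that line, which predicts at most -1.72 for them. They were left out of the line because their scores were high, so a large excess was likely in advance and does not test brightness. Differentiating fish 1, whose array was brighter than both (75th percentile 2259 against 1233 and 1593), scored -1.63. Differentiating fish carry no label of sex, and the design gives no group to test one.

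In the main setting 61.3% of probes differed between female and male juveniles (12710 of 35151 on the value table), which 3 technical explanations could affect. Weak signal of the female arrays is argued against by the 12891 probes above background on all 11 juvenile arrays, of which 71.6% were called, or 116.8% of the share over all probes. Slide is argued against by 82.3% of called probes keeping their call and sign with slide as a block. One scaling stays open in part: under 4 other scalings the lowest share of calls kept with their sign was 68.6%, with the spike-ins, and 92.8%, 88.2% and 91.0% were kept with normexp, quantile and median scaling. Among juveniles aged 485 days alone 19078 probes were called, and 19402 within the first campaign. The difference between the labelled sexes thus held within 1 age class and 1 campaign, while the number of probes depended on the scaling.

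In 4 comparisons few splits of the same fish gave as many calls as the real groups. With 100 splits, the real one included, no share under 1 in 100 can be shown, so chance is not excluded. Of 100 splits, 2 gave as many calls as undifferentiated against pre-undifferentiated fish (366, highest other 914, from a split that kept the 4 pre-undifferentiated fish together and both fish aged 91 days on the other side), and 1, the real one, as many as differentiating against undifferentiated (7058, highest other 6376), female juveniles against differentiating fish (21841, highest other 14477) and female against male juveniles (23156, highest other 13221). For male juveniles against differentiating fish every split gives at least the real 0, so the splits could not test that count. The highest other count was 7896, from 1 split that did not follow the groups. That split put differentiating fish 1, 2, 5 and 7 with male juvenile 1, and had 2 arrays of the second campaign on that side and 4 on the other.

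Of 90 groups of values tested for a fish far from the others, 5 stood out, where chance gives 4.5. Male juvenile 1 had a score of -1.83, against -3.25 to -3.02 in the other males. Female juvenile 6 had 1.38 for R4_6870 (others from 2.15), 5.81 for R4_22405r.1 (others from 6.55) and 4.49 for R4_51131 (others from 6.29). Female juvenile 1, whose array had the fewest probes above background, had -0.92 for R4_12965.1 (others up to -5.01). The difference between the sexes differed between juveniles aged 485 days and aged 309 to 315 days in 1 probe. That between male juveniles and differentiating fish differed between scan campaigns in 4 probes, and in 12 with the files assigned as in the value table.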

How the results depend on the processing

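Campaign, spike-in and assignment alternatives, and leaving out the fish aged 91 days from differentiating against undifferentiated fish and from the score, were chosen after seeing the data. In the order undifferentiated against pre-undifferentiated, differentiating against undifferentiated, male juveniles against differentiating, female juveniles against differentiating and female against male juveniles, counts were 366, 7058, 0, 21841 and 23156. The causes of the shifts below were not tested, except where fewer fish enter. Undifferentiated against pre-undifferentiated gave 4823 with array weights, 108 with slide as a random block, 242 without the fish aged 91 days, 654 with the campaign as a block, 15792 in campaign 2 and 230 with the files assigned as in the value table. Differentiating against undifferentiated gave 10943 with normexp, 3959 with only the 2 groups, 13362 with array weights, 3838 with slide as a block, 10908 without the fish aged 91 days, 10876 without the 4 disputed arrays, 0 in campaign 2 and 26162 with spike-ins. The value table, which carries its own assignment of arrays and blanks for up to 62.6% of a column, gave 6112 there, 4540 higher and 1572 lower. Male juveniles against differentiating gave 1 with normexp, 52 with the value table, 83 with array weights, 1 with the campaign as a block, 3 in campaign 2 and 18 with the files assigned as in the value table. Female juveniles against differentiating gave 13969 with the value table (3184 higher, 10785 lower) and 10902 with slide as a block. Female against male juveniles gave 12710 with the value table and 11762 among juveniles aged 309 to 315 days. Leaving out 1 fish gave 131 to 467, 5202 to 8823, 0 to 2, 20112 to 23196 and 21742 to 23903. The score's spread (1.35, exact p = 0.0169 before and 0.0508 after adjustment, short of the threshold) had an unadjusted exact p above 0.05 with normexp (1.08, exact p = 0.119), without the fish aged 91 days (1.44, exact p = 0.106) and without the 4 disputed arrays (1.17, exact p = 0.134), and ranged from 0.85 to 1.46 when 1 fish was left out, with such a p in 11 of 15 cases. It was 1.42 (unadjusted exact p = 0.0146) with the files assigned as in the value table, 1.56 with quantile, 1.22 with median scaling and 1.14 with 50 probes.

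Of 511 pairs of a named probe and an alternative, 489 kept direction and call, 22 kept direction only and 0 reversed. The named probes were chosen as the largest changes with no overlap between the groups, so leaving out a fish could not reverse them. The 2-fold setting reuses the main fit, so much of the tally was fixed in advance. R4_25357 lost its call in 12 of 27. The median over all probes shifted by over 0.1 in log2 in female juveniles with median scaling (0.32 against both groups) and quantile normalization (0.12 and 0.15 against differentiating fish and males), with normexp (-0.16 in differentiating against undifferentiated fish and 0.10 in male juveniles against differentiating fish) and with spike-ins (-0.16, 1.31, -0.39, 0.71 in the first 4 comparisons, and more than 1 between the sexes).

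Same-numbered undifferentiated and differentiating fish 1 to 4, and male and female juveniles 1, 3 and 4, shared a slide (see slide as a block), but nothing in the labels makes them the same animal, and deviations of same-numbered fish correlated above 0.1 in 1 of 4, 3 of 7, 3 of 5, 1 of 6 and 0 of 5 pairs. The fit with the replicate number as a block gave 280, 7717, 0, 21555 and 23241. Alternatives for gene lists and for other probes of a gene were not run, since no probe has a gene name, and slide as a fixed block gave no value for pre-undifferentiated fish. Weak signal limits female juvenile 1 (15099 probes above background); without it female against male juveniles gave 23903.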

Other observations

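Probe pairs on opposite strands of 1 contig, named alike in the files but for an r, were used to ask whether the strands moved apart between the sexes. Over 797 pairs the log2 differences between female and male juveniles correlated positively (Pearson r 0.305 across probes, which are not independent replicates), outside the range of 1000 random pairings (-0.128 to 0.106). Of 269 pairs with both strands called, 195 moved the same way and 74 opposite ways. Among the 149 pairs that overlap by at least 20 bases r was 0.188, inside the random range (-0.236 to 0.242), and of 47 with both strands called 16 moved opposite ways. The contigs' gene content was not analysed here.

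Whole-array profiles of differentiating fish varied in which juveniles they resembled. The arrays deposited as differentiating fish 5 and 7 had mean correlations of 0.916 and 0.911 with the female juveniles and 0.699 and 0.730 with the males. For differentiating fish 2, 3, 6 and 8 the values were 0.638, 0.635, 0.629 and 0.611 with females and 0.885, 0.895, 0.889 and 0.888 with males. Differentiating fish 1 and 4 had 0.736 and 0.746 with females, and 0.846 and 0.858 with males. Probe R4_626 read 7.05 and 6.39 on the arrays of fish 5 and 7, and between -5.15 and 2.07 on the other 6.

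The spike-in signal relative to the array's 75th percentile (log2) was 0.41 ± 0.35 (SD, n = 4) in pre-undifferentiated fish, 0.57 ± 0.38 (n = 7) in undifferentiated fish, -0.74 ± 0.64 (n = 8) in differentiating fish, -0.34 ± 0.28 (n = 5) in male juveniles and -1.45 ± 0.76 (n = 6) in female juveniles. Differences between these groups were not tested.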
